A study of Mus musculus with 8 samples.

How the data were processed

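DNA methylation was measured by whole-genome bisulfite sequencing (MethylC-seq) in 8 libraries of immortalised mouse embryonic fibroblasts (iMEFs). Bisulfite turns unmethylated cytosine into a base read as thymine and leaves methylated cytosine as it is, so each read over a CpG site calls that site methylated or unmethylated. The libraries fall into 4 groups of n = 2, per the labels: wild-type cells with the solvent DMSO (WT), a line labelled TKO with DMSO, a line labelled 5KO with DMSO, and the 5KO line with DS3201 (valemetostat, an inhibitor of the H3K27 methyltransferases EZH1 and EZH2). The labels do not name the deleted genes. In what is known of the study, the TKO line lacks the H3K9 methyltransferases Setdb1, Suv39h1 and Suv39h2, and the 5KO line lacks Ehmt1 and Ehmt2 as well.

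Per the labels' protocols, genomic DNA was sheared, ligated to adapters, treated with bisulfite and amplified by PCR. Per the submitters' processing notes, Trim Galore 0.3.7 and Bismark 0.14.1 were used with the GRCm38 (mm10) build. The settings, the removal of PCR duplicates, the measured bisulfite conversion and any RNase step are not given in the sources used here. Each deposited file lists CpG sites with the methylation fraction, the count of methylated calls and the count of unmethylated calls that the authors derived from their alignments. The deposited fraction equalled the methylated count over all calls at every site (largest difference 0.0), and no position was listed more than once. Every listed site had at least 1 call, so a site without reads is missing from the list rather than 0. Between 2 and 39 entries per library that were not on the plus strand were left out. PCR copies cannot be recognised in such counts, and reads of any unconverted nucleic acid count as methylated. A pair of groups that differ in such reads would therefore differ in apparent methylation.

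Calls were summed per library over chromosomes 1 to 19 and X. The total was 39,728,456 to 55,377,857 calls per library, a mean of 1.97 to 2.74 calls over the 20,215,823 sites called in any library, so single sites were not tested. Calls were summed over 3 kinds of region instead: 10-kb bins, windows at gene ends, and gene bodies. The gene table used (RefSeq, GRCm38.p6) gives gene starts and ends but no strand or exons. Promoters, planned from the upstream side of each gene, were therefore replaced by a window at the gene end with more CpG sites, reaching 1000 bp outward and 500 bp into the gene. Of 34,328 genes, 32,822 had more sites at one end and 1,506 had equal numbers. CpG islands and repeat classes were not analysed here, and neither was the exonic or intronic position of a site. Coordinates are 1-based GRCm38 positions.

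Per region, methylated and unmethylated calls of all 8 libraries were fitted with a quasi-binomial model with 1 level per group and 4 residual degrees of freedom. The overdispersion was moderated across regions as in limma and kept at 1 or more. Differences were tested with a two-sided F test and Benjamini-Hochberg adjustment within each comparison. Below, a region is called lower or higher at an adjusted p under 0.05 with a difference of at least 10 percentage points, among regions with at least 20 calls in every library. Adjusted p-values without another tool's name are from this model, moderated as in limma. The counts varied more than binomial sampling allows, with a prior overdispersion of 3.45 for bins, 5.03 for windows and 5.51 for gene bodies. The median number of calls per library was 142 in a bin (117 to 168 across libraries), 87 in a window (62 to 140) and 389 in a gene body (325 to 497). Genome-wide levels were compared with an exact two-sided permutation test, which cannot go below p = 0.333 with 2 libraries against 2. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Each genotype was 1 cell line, so a difference between lines cannot be assigned to the deleted genes rather than to the clone.

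The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1 and edgeR 4.0.16. Figures were drawn with matplotlib 3.10.9. The model was tested on simulated data for the comparison of TKO with WT, with 100 changed regions of each size. It recovered 18% of bins changed by 20 points and 82% of those changed by 40 points, with 5 false calls. For gene bodies these shares were 57% and 79%, with 8 false calls. For gene-end windows they were 0% and 0%, with 0 false calls, so a low number of windows in that comparison says little.

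The comparisons were TKO with WT, 5KO with WT, 5KO with TKO, and DS3201-treated 5KO with untreated 5KO. The groups, comparisons, model, thresholds, gene lists and naming rule were chosen before the data were examined. The 17 lists were imprinted genes, germline genes, developmental transcription factor and signalling genes typical of Polycomb targets, fibroblast, epithelial and immune marker genes, housekeeping genes, H3K9 methylation pathway genes, Polycomb repressive complex 2 (PRC2) genes, DNA methylation machinery, Hox genes, olfactory receptors, vomeronasal receptors, Zfp zinc finger genes, clustered protocadherins, keratin-associated protein genes and defensins. Each list was tested with limma's camera on log2((methylated + 1)/(unmethylated + 1)) with a preset correlation of 0.01, adjusted over the lists and comparisons of a region type. Camera asks whether a list's members moved relative to the other genes, so its direction can differ from the sign of the members' own change. The test was repeated with an estimated correlation.

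Genes are named by a fixed rule. Among called regions of genes other than predicted ones (Gm numbers and Rik symbols), with at least 5 sites and with both libraries of 1 group beyond both of the other, the 10 largest rises and 10 largest falls per comparison are eligible. From each list come the 2 members with the largest absolute difference among called members, or among tested members where none was called. All called members of the H3K9, PRC2 and DNA methylation machinery lists are added. For bins, the 3 longest runs of adjacent called bins per direction are given. Named outside this rule, after their values were seen, were Junb, Ubb and Col1a1 for their call profiles and the genes behind counts of 5 or fewer.

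Results were also computed with another bin size, window size, call minimum and minimum difference, with limma and edgeR in place of the model, with calls thinned to the shallowest library, with sites of extreme coverage removed (above 56.0 summed calls), with genome-wide levels corrected for the apparent methylation of mitochondrial DNA, with the replicate number as a block, and with each library left out in turn. Chosen after seeing the data were the same mitochondrial correction of regions, gene bodies as a region type, sites with at most 5 CpG sites within 100 bp, sites and bins outside genes, 100-kb bins of sites over 1 kb from any gene, the part of a gene-end window outside genes, the other gene end, fits of only the 2 groups compared, and regions without excess calls in untreated 5KO cells. Results for some single genes are not reported here.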

Results

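CpG methylation was measured in 8 bisulfite libraries of mouse embryonic fibroblasts: WT cells, a TKO line that lacks 3 H3K9 methyltransferases in what is known of the study, a 5KO line that lacks 2 more, and 5KO cells treated with DS3201, with 2 libraries per group. The WT libraries held 40,325,896 and 51,649,254 calls, the TKO libraries 45,292,083 and 40,567,123, the untreated 5KO libraries 55,377,857 and 45,872,845, and the DS3201-treated libraries 39,728,456 and 53,408,549. Each library had calls at 59.3% to 72.9% of the sites. Levels of 10-kb bins correlated across bins between the 2 libraries of a group at r = 0.794 in WT, 0.902 in TKO, 0.932 in 5KO and 0.920 in DS3201-treated cells. The mean absolute difference between the 2 libraries was 7.89 to 8.47 points per bin. Values after ± are SDs over n = 2 libraries.

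The deleted genes were looked at first, as runs of CpG sites with calls in both WT libraries and in neither library of another group. Setdb1 had a longest run of 3 sites in TKO cells and 4 in 5KO cells, and 56.3% and 42.7% of 21,631 genes had runs at least as long. Suv39h1 had 9 sites in TKO and 10 in untreated 5KO cells (8.94% and 8.91% of genes), and Ehmt2 had 10 in untreated 5KO cells (8.91%), but DS3201-treated cells of the same line had 2 and 4. Suv39h2 had 6 sites in TKO (22.9%) and 0 in untreated 5KO cells, and Ehmt1 had 4 in untreated 5KO cells (42.7%). The longest run at any of 8 histone methyltransferase genes was 18 sites of Ezh2 in untreated 5KO cells (chromosome 6, 47,594,263 to 47,594,380), and 2.27% of genes had one as long. Missing calls at this depth cannot show a deletion of a few exons, so these values do not check the labels.

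Of all calls at CpG sites, 73.8% ± 0.15 were methylated in WT cells, 64.7% ± 0.27 in TKO cells and 56.5% ± 0.23 in 5KO cells. DS3201-treated 5KO cells stood at 58.6% ± 0.34. TKO cells were thus at −9.15 points from WT, 5KO cells at −17.4 points from WT and −8.24 points from TKO, and DS3201-treated cells at +2.15 points from untreated 5KO cells. Each difference exceeded the spread between libraries, and each reached the smallest p that 2 libraries against 2 can give (exact permutation test, two-sided, p = 0.333). On the sites with calls in all 8 libraries the difference with DS3201 was −0.0868 points.

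In TKO and 5KO cells the losses against WT were larger outside genes than in gene bodies or gene-end windows. Outside genes and gene-end windows, with sites of extreme coverage removed, the level was 69.4% ± 0.10 in WT, 55.2% ± 1.38 in TKO, 42.8% ± 1.57 in 5KO and 48.6% ± 0.81 in DS3201-treated cells. Gene bodies stood at 77.8% ± 0.06, 70.0% ± 0.44, 62.4% ± 0.59 and 64.7% ± 0.28 in the same order. Gene-end windows stood at 40.5% ± 1.02, 37.4% ± 3.14, 41.0% ± 4.88 and 31.5% ± 1.45. Sites with more than 15 CpG sites within 100 bp, mostly in CpG-rich stretches of low methylation, were at 17.3% ± 0.65 in WT and 22.0% ± 1.83 in TKO. The same sites were at 35.6% ± 7.07 in untreated 5KO and 19.96% ± 0.46 in DS3201-treated cells. In each group the library with fewer calls on these sites had the higher level, in untreated 5KO 40.6% at 557,922 calls and 30.6% at 1,514,371. From WT to untreated 5KO such sites went from 16.6% ± 0.87 to 37.0% ± 7.33 in genes and from 20.7% ± 0.47 to 27.9% ± 5.83 outside them. Those over 5 kb from any gene went from 64.2% ± 1.67 to 61.1% ± 4.25. The X chromosome was at 67.1% in WT, 51.2% in TKO, 42.3% in 5KO and 46.3% in DS3201-treated cells.

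**Figure D1:**
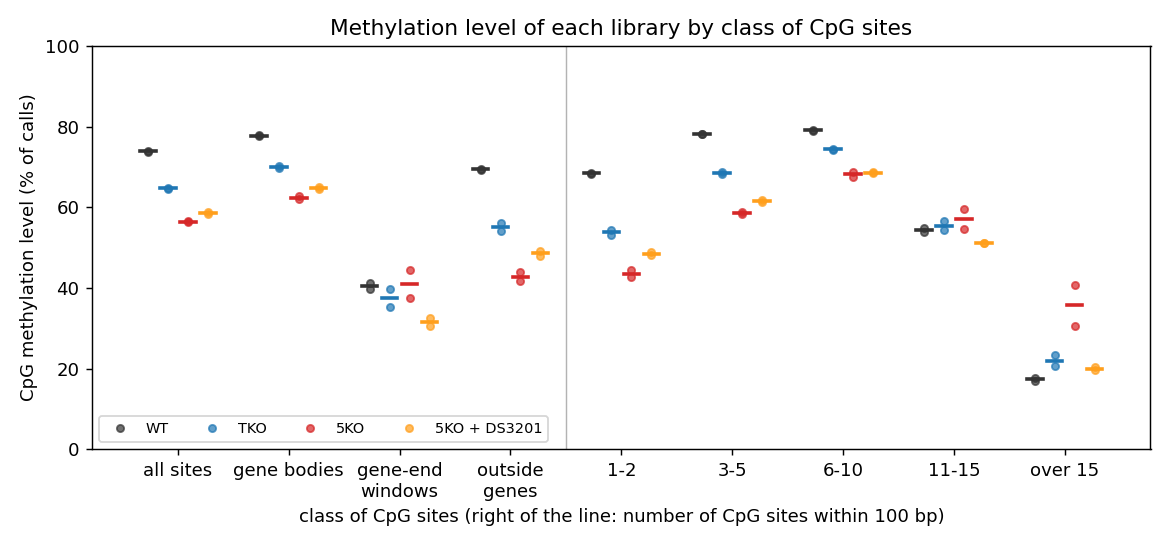
Methylation level in percent (vertical axis) by class of CpG site (horizontal axis), with 1 point per library and bars for the mean of the 2 libraries of each group. Sites outside genes step down from 69.4% in WT to 55.2% in TKO and 42.8% in 5KO cells, while the densest sites are highest in untreated 5KO cells (35.6%, with 7.07 between libraries as SD).

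TKO was compared with WT to ask where methylation differs in a line that, in what is known of the study, lacks Setdb1, Suv39h1 and Suv39h2. Methylation fell over long domains: 69,513 of 241,050 bins (28.8%) were lower in TKO cells and 1,180 (0.49%) were higher, with a median difference of −12.2 points. The longest run of lower bins covered 1,160 kb of chromosome 14 (116,930,001 to 118,090,000), at Gpc6, which encodes a cell-surface proteoglycan, and Dct, a gene of melanin synthesis, and went from 80.3% ± 0.51 to 36.3% ± 1.79. A run of 650 kb without a protein-coding gene on the same chromosome (100,290,001 to 100,940,000) went from 75.9% ± 0.02 to 28.8% ± 0.46. A run of 640 kb on chromosome 11 (35,130,001 to 35,770,000) at Slit3, an axon guidance gene, and Pank3, a kinase of coenzyme A synthesis, went from 83.7% ± 0.58 to 46.8% ± 1.92. Higher bins came in short runs, the longest being 40 kb in Dnah7a, an axonemal dynein gene (chromosome 1, 53,650,001 to 53,690,000), from 61.3% ± 5.79 to 90.04% ± 1.25. Gabbr2, which encodes a GABA-B receptor subunit, had a run of 40 kb (chromosome 4, 46,710,001 to 46,750,000) from 69.2% ± 0.94 to 86.1% ± 3.06. Bins without a protein-coding gene were lower in 35.2% of cases and bins with one in 21.7%. The lower share was 18.8% without WT replicate 1, 13.5% without WT replicate 2, 13.7% without TKO replicate 1 and 11.4% without TKO replicate 2, and the higher share 0.446%, 0.324%, 0.309% and 0.2%.

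Gene bodies showed the same direction in TKO cells, with 4,063 of 29,651 lower and 158 higher. The body of Fv1, a restriction factor against murine leukaemia virus (chromosome 4, 147,868,979 to 147,870,358), fell from 88.6% ± 3.78 to 2.73% ± 3.86. Nhs on the X chromosome (161,833,290 to 162,159,441) fell from 85.9% ± 0.68 to 31.2% ± 4.56 over 1,944 sites (adjusted p = 1.07e-05). Spink11, Esp5, Speer4c, Defb15, Amigo2, Hnrnpa0, Cd3eap and Fcer1a, which encodes the alpha chain of the high-affinity IgE receptor, were the other large falls, by values between −67.6 points for Spink11 and −50.8 points for Fcer1a. Of the large rises, Gng3, which encodes a G protein gamma subunit, went from 36.9% ± 8.09 to 93.1% ± 9.75. The homeobox genes Nkx2-3 (17.5% ± 5.92 to 69.2% ± 17.7), Hoxa13 (2.86% ± 4.04 to 53.4% ± 18.7) and Lhx1 (18.5% ± 0.32 to 63.3% ± 10.9) rose as well. Prr18, Tspyl5, Lrrc26, Nudt16l1, Dmrta2 and Pcsk1n completed the 10 largest rises, by 52.6 points for Prr18 down to 42.5 points for Pcsk1n. Of 14,734 gene-end windows, 1 was called, that of the predicted gene Gm40237 on chromosome 4 (83.1% ± 0.64 to 58.8% ± 0.61), named after its values were seen. The model called 0 windows higher, edgeR called 0 and limma 0.014% of windows, and 1,536 windows were at an unadjusted p under 0.05. In the parts of windows outside genes 1 of 3,028 was higher, beside Bdnf, which encodes a neurotrophin (chromosome 2, 109,673,700 to 109,674,699; 11.6% ± 4.73 to 80.5% ± 4.98; adjusted p = 0.0318), named after its values were seen. Of gene bodies 14.2% were called, and 8.95% without WT replicate 1, 7.05% without WT replicate 2, 7.51% without TKO replicate 1 and 8.14% without TKO replicate 2. The call at Gm40237 was lost without WT replicate 1, WT replicate 2 or TKO replicate 1, and in a fit of the 2 groups alone.

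Developmental genes had higher bodies in TKO cells: 21 of 118 tested were higher and 2 lower (28 and 2 adjusted over the list alone), and the list mean went from 45.1% ± 0.36 to 55.3% ± 1.71. The list stood above other genes in camera (adjusted p = 1.08e-28; adjusted p = 0.0233 with an estimated correlation). Foxl2, a transcription factor gene of the ovary, went from 14.5% ± 0.76 to 51.9% ± 5.22. Calls over these bodies, relative to gene bodies of like CpG density, were 0.944 ± 0.003 in WT and 0.925 ± 0.041 in TKO. In Hox genes 3 of 37 bodies were higher and 0 lower by the quasi-binomial model (3 and 0 adjusted over the list alone; camera adjusted p = 5.58e-10, adjusted p = 0.0233 with an estimated correlation), with Hoxb5 from 64.3% ± 4.47 to 93.5% ± 3.64. In the developmental list's gene-end windows the mean went from 29.9% ± 0.33 to 43.6% ± 2.53 with 0 of 79 called by the quasi-binomial model (1 adjusted over the list alone; camera adjusted p = 2.29e-08, adjusted p = 0.128 with an estimated correlation).

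In TKO cells, of 109 olfactory receptor bodies with enough calls, out of 1,108 in the gene table, 11 were lower (7 adjusted over the list alone), and their mean went from 60.5% ± 1.68 to 39.4% ± 2.12. Of 108 vomeronasal receptor bodies 28 were lower (41 adjusted over the list alone), with a mean from 49.9% ± 0.21 to 30.7% ± 0.44. Both stood below other genes in camera (adjusted p = 4.29e-05 and 2.67e-05), and both kept an adjusted p = 0.0233 with an estimated correlation. Olfr78 went from 54.5% ± 0.12 to 15.9% ± 4.21 and Vmn2r67 from 60.1% ± 0.57 to 18.7% ± 2.44. Of 29 defensin bodies 6 were lower (10 adjusted over the list alone; camera adjusted p = 0.000952, adjusted p = 0.126 with an estimated correlation). Clustered protocadherins, cell adhesion genes of neurons, had 18 of 57 bodies lower (22 adjusted over the list alone; camera adjusted p = 0.380, adjusted p = 0.830 with an estimated correlation), among them Pcdhb6 from 69.3% ± 0.18 to 31.8% ± 12.5. Immune markers had 4 of 18 lower (4 adjusted over the list alone), with Lcp2, a T cell signalling adaptor, from 60.9% ± 3.96 to 29.0% ± 0.43. The Zfp list had 32 of 389 lower (26 adjusted over the list alone), with Zfp747 from 92.9% ± 4.87 to 42.8% ± 8.73. Camera gave adjusted p = 0.0320 for immune markers and 0.567 for the Zfp list, and adjusted p = 0.153 and 0.820 with an estimated correlation. Imprinted genes had 6 of 42 lower (7 adjusted over the list alone), with Usp29 from 62.5% ± 4.0 to 30.3% ± 2.11. Germline genes had 3 of 46 lower (1 adjusted over the list alone), with Piwil1, a gene of the piRNA pathway, from 72.1% ± 1.93 to 43.1% ± 4.67. Camera placed imprinted bodies above other genes although their median was −4.3 points (adjusted p = 0.349; adjusted p = 0.496 with an estimated correlation), and germline bodies had adjusted p = 0.917 (adjusted p = 0.926 with an estimated correlation).

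The remaining lists had few calls in TKO cells. Housekeeping bodies had 1 lower, the proteasome gene Psmb4 (81.1% ± 13.8 to 30.7% ± 10.8), and 1 higher, the elongation factor gene Eef1a1 (65.3% ± 1.10 to 76.9% ± 2.84), of 30, and 0 adjusted over the list alone. Their median was 1.74 points and their mean −2.92 points, and camera placed them above other genes (adjusted p = 0.00112; adjusted p = 0.121 with an estimated correlation). Epithelial bodies had Krt5 lower (to 51.5% ± 6.53) and the tight junction gene Cldn7 higher (54.0% ± 0.06 to 73.2% ± 3.95) of 20, and 0 adjusted over the list alone (camera adjusted p = 0.135, adjusted p = 0.249 with an estimated correlation). In fibroblast markers Dcn was the 1 lower of 30 (1 adjusted over the list alone; 83.6% ± 3.49 to 67.9% ± 2.36; camera adjusted p = 0.303, adjusted p = 0.421 with an estimated correlation). The model called 0 bodies of the 21 H3K9, 13 PRC2 and 15 DNA methylation machinery genes, and 0 adjusted over each list alone (camera adjusted p = 0.170, 0.134 and 0.284; adjusted p = 0.490, 0.421 and 0.619 with an estimated correlation). Among windows, olfactory receptors stood below other genes (0 of 44 called by the model, camera adjusted p = 1.29e-06, adjusted p = 0.134 with an estimated correlation) and Hox genes above (0 of 26; 0.00104 and 0.177), while protocadherin windows had a median of 10.6 points and a mean of −1.0 points (0 of 39; 0.0756 and 0.679).

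5KO was compared with WT to ask where methylation differs in the line that lacks Ehmt1 and Ehmt2 as well. Methylation fell over most of the genome: 152,434 bins (63.2%) were lower in 5KO cells and 2,504 (1.04%) higher, with a median difference of −25.2 points. Set against that median at the same adjusted p against WT, 75,034 bins (31.1%) lay at least 10 points below it. Another 11,309 (4.69%) lay at least 10 points above it, which can include bins lower than WT. No difference from the median was tested. Bins under 20% methylation made up 0.104% of bins in WT, 8.78% in TKO, 23.3% in 5KO and 14.4% in DS3201-treated cells. The longest lower run took 1,810 kb of chromosome 14 (99,630,001 to 101,440,000), with Klf12, a transcriptional repressor gene, and Prr30, and went from 77.7% ± 0.30 in WT to 37.9% ± 0.26 in TKO and 21.9% ± 1.23 in 5KO cells. A run of 1,760 kb on chromosome 12 (106,230,001 to 107,990,000) at Bcl11b, a T cell transcription factor gene, went from 62.6% ± 0.14 to 24.3% ± 0.67. A run of 1,570 kb on chromosome 4 (152,390,001 to 153,960,000) at Chd5, Kcnab2, Nphp4 and Ajap1 went from 63.4% ± 0.09 to 27.7% ± 0.21. Higher runs reached 70 kb and lay in Dnah7a (59.6% ± 0.11 to 86.9% ± 1.2) and at Ceacam10 (chromosome 7, 24,780,001 to 24,840,000; 67.7% ± 2.82 to 86.7% ± 0.39). Of bins without any gene, 78,968 of 97,228 were lower and 396 higher.

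**Figure D2:**
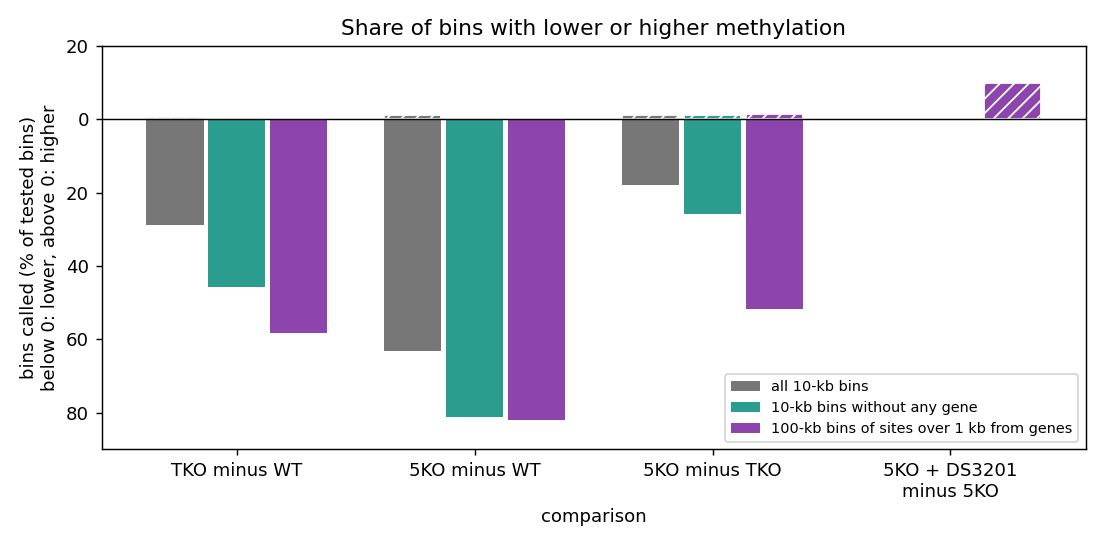
Share of bins in percent (vertical axis) called lower (bars below 0) and higher (hatched bars above 0) in each comparison, for all 10-kb bins, 10-kb bins without any gene, and 100-kb bins of sites over 1 kb from any gene. Lower bins make up 28.8%, 63.2% and 18.02% of all 10-kb bins in the comparisons of TKO with WT, 5KO with WT and 5KO with TKO, and higher 100-kb bins away from genes make up 9.79% with DS3201.

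Gene bodies in 5KO cells were lower at 10,821 loci and higher at 663. Nhs fell to 16.1% ± 2.39 (adjusted p = 4.6e-07), Lrrc30 from 80.8% ± 5.80 to 4.29% ± 6.06, and Adam26a, a member of a testis metalloprotease-like family, from 68.5% ± 2.17 to 4.17% ± 1.02. Spink11, Defb26, Speer4c, Kap, Nat1, Ftdc1 and the olfactory receptor gene Olfr561 also fell, by values between −71.9 points for Spink11 and −62.3 points for Olfr561. The rises included Ubb, a ubiquitin gene (21.2% ± 11.02 to 87.8% ± 13.8), the immediate early gene Junb (22.3% ± 2.52 to 87.3% ± 9.04), the linker histone gene H1f10 (0.5% ± 0.71 to 83.4% ± 23.1) and the forkhead gene Foxd1 (4.08% ± 4.03 to 69.2% ± 7.0). Nsmce3, Misp3 (6.89% ± 0.19 to 71.3% ± 40.6, with the 2 5KO libraries far apart), Ier3, Gng13, Nudt16l1 and Hmgn2 rose by 60.3 to 65.9 points. Of these genes, Ubb and Junb held 613 and 1,328 methylated calls in the 2 untreated 5KO libraries against 97 and 120 in the WT libraries.

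Gene-end windows went both ways in 5KO cells, with 49 lower and 159 higher of 14,734. Lower windows included Eva1a (91.8% ± 6.12 to 6.36% ± 6.72), Cdh8, a cadherin gene (76.8% ± 1.06 to 20.8% ± 1.57), Cdkn2b, a cell cycle inhibitor gene (76.8% ± 6.44 to 26.3% ± 8.15), and Krt1, an epidermal keratin gene (80.1% ± 5.52 to 38.1% ± 6.20). Fam240b, Sdr9c7, Tenm3, Wfdc16 and Glp2r were the other large falls of the kind named here. Higher windows included Angptl4, an inhibitor of lipoprotein lipase, at 2.17% ± 3.07 in WT, 69.2% ± 0.72 in TKO, 82.2% ± 2.34 in 5KO and 83.1% ± 6.15 in DS3201-treated cells. Sqstm1, an autophagy receptor gene, went from 9.23% ± 12.6 to 94.9% ± 4.5 and stood at 2.64% ± 0.31 with DS3201. Col1a2, a collagen gene, stood at 17.95% ± 9.35 in WT, 76.3% ± 21.2 in TKO, 91.5% ± 0.37 in 5KO and 20.2% ± 10.1 with DS3201. Rnf217, H1f2, Mogs, Ubxn4, Vcp, Ptms and Faf1 rose by 70.1 to 81.0 points. The share of windows called was 1.41%, with 2.43% by limma (240 lower and 118 higher) and 0% by edgeR. It was 0.054% with the replicate number as a block, 0.014% with the mitochondrial correction and 0.0% in a quasi-binomial fit of the 2 groups alone. Windows of 2000 bp on each side of the gene end had 2,395 lower and 641 higher, and of the windows as defined 3,393 had an unadjusted p under 0.05. Leaving out a library gave 0.007% without WT replicate 1, 0% without WT replicate 2, 2.29% without 5KO replicate 1 and 1.10% without 5KO replicate 2. In the parts outside genes 28 of the 159 higher windows had enough calls, and 0 of these were higher by the quasi-binomial model, with a median of 29.5 points. Gm40237 was the 1 lower of all 3,028 (81.6% ± 0.52 to 52.1% ± 0.51), named after its values were seen. This part of its window also had high coverage, with at least 522 calls in every library over 24 sites. Of the 3,028, 573 had an unadjusted p under 0.05.

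In 5KO cells olfactory receptor bodies were lower in 68 of 109 (79 adjusted over the list alone), with a mean of 27.2% ± 0.09. Vomeronasal receptor bodies were lower in 79 and higher in 3 of 108 (81 and 3 adjusted over the list alone), with a mean of 22.7% ± 0.37. Camera gave adjusted p = 3.70e-06 and 9.77e-05, and adjusted p = 0.0233 for both with an estimated correlation. Vmn2r51 went from 55.0% ± 0.15 to 2.47% ± 1.88. Germline genes were lower in 30 of 46 bodies (33 adjusted over the list alone), with a mean from 76.6% ± 1.17 to 55.8% ± 0.68 (camera adjusted p = 0.000408, adjusted p = 0.0531 with an estimated correlation). They were led by Syce1, a gene of the synaptonemal complex (71.9% ± 3.09 to 31.0% ± 12.9), and Smc1b, a meiotic cohesin gene (70.8% ± 1.89 to 31.8% ± 7.41). Defensins were lower in 21 of 29 (22 adjusted over the list alone; camera adjusted p = 0.00118, adjusted p = 0.126 with an estimated correlation), immune markers in 13 of 18 (15 alone; 0.0167 and 0.126 for the same tests) and protocadherins in 36 of 57 (39 alone; 0.0140 and 0.515). Imprinted genes were lower in 13 of 42 (13 adjusted over the list alone), with Meg3 from 82.4% ± 1.07 to 36.2% ± 6.89; camera placed this list above other genes while its median was −5.35 points (adjusted p = 0.507; adjusted p = 0.622 with an estimated correlation). Epithelial markers were lower in 6 of 20 bodies (6 adjusted over the list alone), with Krt5 from 74.3% ± 2.28 to 41.8% ± 0.65. The Zfp list was lower in 73 of 389 with 7 higher (52 and 3 adjusted over the list alone), with Zfp521 from 82.8% ± 0.19 to 25.5% ± 0.91. Camera gave adjusted p = 0.987 for epithelial markers and, above other genes though the median was −4.27 points, 0.00168 for the Zfp list, and adjusted p = 0.986 and 0.249 with an estimated correlation. Of 15 DNA methylation machinery genes 3 were lower (3 adjusted over the list alone; camera adjusted p = 0.0687, adjusted p = 0.421 with an estimated correlation), Dnmt3l (73.1% ± 4.61 to 41.7% ± 5.24), Tet1 (81.5% ± 5.65 to 56.01% ± 0.28) and Dnmt3b (81.9% ± 4.95 to 61.3% ± 2.24). The same 3 genes were lower than in TKO cells. Keratin-associated protein genes had 2 tested bodies, too few for camera, and 0 were called by the quasi-binomial model. Their 4 tested windows went from 78.3% ± 2.30 to 33.1% ± 4.75 (0 called, 4 lower adjusted over the list alone; camera adjusted p = 0.00497, adjusted p = 0.173 with an estimated correlation). Olfactory receptor windows had 0 of 44 called by the model and 15 lower adjusted over the list alone (camera adjusted p = 1.21e-09, adjusted p = 0.128 with an estimated correlation), and protocadherin windows a median of 7.02 points and a mean of −2.43 points (0 of 39; 0.924 and 0.972).

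Developmental gene bodies in 5KO cells were higher in 28 and lower in 11 of 118 (27 and 11 adjusted over the list alone), with a mean of 53.7% ± 0.04 in 5KO cells (camera adjusted p = 8.33e-18, adjusted p = 0.0233 with an estimated correlation). Lhx1 went from 18.5% ± 0.32 to 63.0% ± 1.86, and stood at 68.9% ± 2.52 with DS3201. Hox bodies were higher in 6 and lower in 5 of 37 (4 and 5 adjusted over the list alone; camera adjusted p = 1.70e-06, adjusted p = 0.0233 with an estimated correlation). The gene-end windows of Prox1 (7.65% ± 0.14 to 63.0% ± 5.19) and Lhx1 (9.07% ± 2.82 to 52.4% ± 2.55) were the 2 called of 79 developmental windows (15 adjusted over the list alone; camera adjusted p = 3.06e-05, adjusted p = 0.134 with an estimated correlation). Housekeeping gene bodies were higher in 9 and lower in 2 of 30 (9 and 2 adjusted over the list alone), with a mean from 57.5% ± 2.06 to 70.9% ± 3.51 (camera adjusted p = 1.23e-12, adjusted p = 0.0233 with an estimated correlation). Calls over housekeeping bodies, relative to bodies of like CpG density, were 1.99 ± 0.27 in untreated 5KO cells, 1.23 ± 0.14 in WT, 1.14 ± 0.03 in TKO and 1.09 ± 0.001 with DS3201. Fibroblast marker windows went from 36.0% ± 0.74 to 65.3% ± 2.81, with 1 of 18 called (4 adjusted over the list alone; camera adjusted p = 0.00104, adjusted p = 0.134 with an estimated correlation). Their relative calls were 2.15 ± 0.17 in untreated 5KO cells and 1.05 to 1.14 in the other groups. In fibroblast bodies 3 were higher and 5 lower of 30 (3 and 5 adjusted over the list alone), and Dcn, a proteoglycan gene of the matrix, fell from 83.6% ± 3.49 to 32.4% ± 2.58. Their median was 2.18 points and their mean −0.71 points (camera adjusted p = 0.00202, adjusted p = 0.101 with an estimated correlation). Of 21 H3K9 pathway bodies Trim28, a corepressor gene, was higher (57.7% ± 4.01 to 75.9% ± 3.42), and of 13 PRC2 bodies Kdm6b, an H3K27 demethylase gene (44.1% ± 0.67 to 60.3% ± 1.12), with 0 in each adjusted over the list alone (camera adjusted p = 0.00203 and 0.000936; adjusted p = 0.186 and 0.153 with an estimated correlation). Single windows were higher in the H3K9 list at Cbx3 (0.0% ± 0.0 to 37.0% ± 8.55), in the imprinted list at Zrsr1 (23.0% ± 5.22 to 78.1% ± 4.04) and in the housekeeping list at Vcp (1.37% ± 1.93 to 77.1% ± 27.3).

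The bins lower in TKO cells were mostly lower in 5KO cells too. Of the bins tested in both comparisons, 65,077 were lower in both, 528 were higher in both, and 125 changed in opposite directions. Independent lists of the same sizes would share 43,958.3 lower and 12.3 higher bins. In 20 simulations of unchanged groups against the same WT libraries the mean overlap was 0.0. The simulated groups had almost no called bins (means of 0.05 lower in TKO and 0.0 in 5KO), so this overlap sets no baseline. The covariance of the differences was 193.0 against 29.0 in the simulations, and their correlation across bins was 0.721 against 0.489. Part of the excess may come from the shared WT libraries. They were not divided as a test, since that would leave 1 library in each part.

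5KO was compared with TKO to ask what the 5KO line adds to the loss seen in TKO cells. In all, 43,448 bins (18.02%) were lower in 5KO and 2,995 (1.24%) higher, with a median difference of −8.75 points. The longest lower run was 740 kb of chromosome 8 (114,960,001 to 115,700,000) at Wwox, a gene at a common fragile site, which went from 76.5% ± 0.99 in TKO to 45.9% ± 0.66 in 5KO cells and stood at 83.6% ± 0.18 in WT. A run on chromosome 3 (148,990,001 to 149,500,000, no protein-coding gene) went from 71.5% ± 0.41 to 38.7% ± 0.94. Another at Ctnna3 and the neuronal gene Lrrtm3 on chromosome 10 (63,670,001 to 64,090,000) went from 65.4% ± 0.32 to 31.5% ± 1.07. Some domains were higher in 5KO than in TKO and in WT cells. A run of 230 kb without a protein-coding gene on chromosome 17 (69,730,001 to 69,960,000) stood at 61.0% ± 1.31 in WT and 32.1% ± 0.25 in TKO. The same run stood at 77.4% ± 1.4 in 5KO and 77.8% ± 1.23 in DS3201-treated cells. The run at Cadm1, a cell adhesion gene (chromosome 9, 47,640,001 to 47,860,000), went from 48.2% ± 0.81 in TKO to 83.1% ± 1.79 in 5KO cells. A run on chromosome 15 (19,490,001 to 19,640,000, no protein-coding gene) went from 26.4% ± 0.69 to 67.2% ± 1.03. Without TKO replicate 1, TKO replicate 2, 5KO replicate 1 and 5KO replicate 2 in turn, 6.32%, 7.60%, 9.999% and 10.2% of bins were lower and 0.472%, 0.759%, 1.10% and 0.676% higher.

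**Figure D3:**
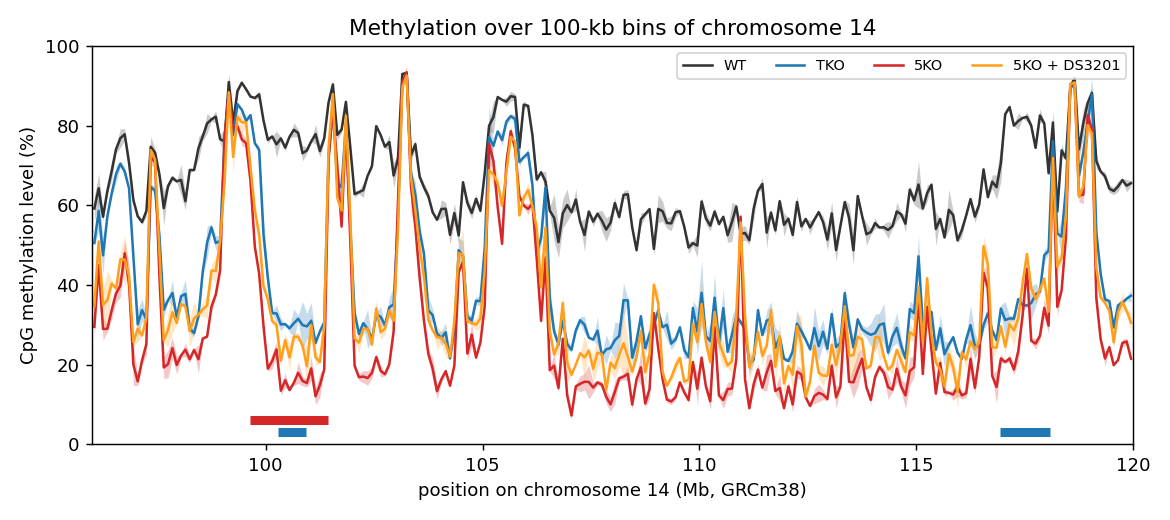
Methylation level in percent (vertical axis) of 100-kb bins along the part of chromosome 14 around Klf12, Gpc6 and Dct (horizontal axis, position), with lines for group means, shading for the range of the 2 libraries, and bars for the longest runs of called bins. The run at Gpc6 and Dct lies at 80.3% in WT and 36.3% in TKO cells, and the run at Klf12 at 77.7% in WT and 21.9% in 5KO cells.

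Gene bodies were lower in 5KO than in TKO cells at 4,581 loci and higher at 585. Epyc, a cartilage proteoglycan gene, fell from 69.1% ± 3.74 to 24.2% ± 4.66 (adjusted p = 0.000331), Fabp7, a brain fatty acid binding protein gene, from 64.0% ± 1.56 to 19.6% ± 6.96, and the C-type lectin gene Clec1b from 76.1% ± 1.04 to 32.0% ± 0.30. Rfpl4b, Clec2e, Clec2h, Rab9b, Pom121l2, Aadacl2fm2 and Pabpc4l also fell, by values from −53.7 points for Rfpl4b to −45.0 points for Pabpc4l. Germline genes were lower in 24 of 46 bodies (27 adjusted over the list alone; camera adjusted p = 1.02e-05, adjusted p = 0.0268 with an estimated correlation), with Ddx4, a germ cell helicase gene, from 74.2% ± 1.19 to 46.3% ± 6.67 and Sohlh2 from 74.0% ± 0.78 to 46.5% ± 3.32. Immune markers were lower in 8 of 18 (8 alone; camera adjusted p = 0.0490, adjusted p = 0.169 with an estimated correlation), protocadherins in 13 of 57 (16 alone; 0.0746 and 0.630), and developmental genes in 13 of 118 with 6 higher (13 and 6 alone; 0.123 and 0.282). Olfactory receptors were lower in 4 of 109 (0 alone; 0.00984 and 0.0700) and vomeronasal receptors in 12 of 108 with 4 higher (8 and 2 alone; 0.0413 and 0.101). Fibroblast bodies went both ways, with Lum (70.9% ± 1.01 to 28.0% ± 4.92) among 4 lower and 5 higher of 30 (4 and 5 alone; 0.00253 and 0.101), and epithelial bodies had 2 lower of 20, Esrp1 and Grhl2 (71.0% ± 2.86 to 48.3% ± 0.72; 2 alone; 0.334 and 0.421). Defensins had 2 of 29 lower (0 alone; 0.0847 and 0.324), Hox bodies 3 lower and 1 higher of 37 (0 alone; 0.233 and 0.310), imprinted bodies 7 lower and 1 higher of 42 (9 and 1 alone; 0.666 and 0.755), and the Zfp list 15 lower and 7 higher of 389 (11 and 2 alone; 2.67e-05 and 0.157). Of gene bodies 17.4% were called, and 8.33% without TKO replicate 1, 11.1% without TKO replicate 2, 11.3% without 5KO replicate 1 and 11.4% without 5KO replicate 2.

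From TKO to 5KO cells the 10 largest rises in gene bodies were in Ier3, Junb and Jund, which are immediate early genes, Ubb, the ribosomal protein genes Rpl12 and Rps15, the translation factor gene Eif5a, the chaperonin gene Hspe1, the splicing factor gene Srsf6, and Hccs, with 59.2 to 67.6 points each. For Rpl12 (3.57% ± 3.56 to 64.6% ± 50.06) the 2 untreated 5KO libraries lay far apart. Housekeeping bodies were higher in 11 of 30 (11 adjusted over the list alone; camera adjusted p = 1.76e-10, adjusted p = 0.0268 with an estimated correlation), with Rplp0 from 46.3% ± 9.44 to 93.2% ± 6.33. Trim28 in the H3K9 list (53.5% ± 14.5 to 75.9% ± 3.42) and Aebp2 in the PRC2 list (65.1% ± 14.1 to 84.6% ± 4.89) were the single called bodies of their lists, with 0 adjusted over the list alone (camera adjusted p = 0.00181 and 0.00160; adjusted p = 0.185 and 0.162 with an estimated correlation). Gene-end windows were higher at 60 of 14,734 genes, the 10 largest being Utp18, Mbtd1, Phf6, Mtpn, Ptms, Rbbp7, Lamp1, Eif3b, Arf4 and Hnrnpd, with Eif3b, a translation initiation gene, from 7.57% ± 6.74 to 79.0% ± 5.19 (adjusted p = 0.00959). The windows of Utp18 (chromosome 11, 93,885,266 to 93,886,766) and Mbtd1 (93,884,850 to 93,886,350) overlap, so they share calls. The model called 0 windows lower, limma and edgeR called 0 in either direction, and 2,216 had an unadjusted p under 0.05. The share called was 0.407%, 0.014% with the mitochondrial correction and 0.0% in a quasi-binomial fit of the 2 groups alone. No window was called without TKO replicate 1 or without TKO replicate 2, while 2.12% were called without 5KO replicate 1 and 1.004% without 5KO replicate 2. Of the 60 windows 18, and of the 585 bodies 106, were among regions where the untreated 5KO libraries held over 1.5 times the calls of like regions, relative to the other groups. Such regions made up 2,329 of all 14,734 windows and 922 of all 29,651 bodies.

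DS3201-treated 5KO cells were compared with untreated cells of the same line to ask where methylation differs when EZH1 and EZH2 are inhibited as well. Away from genes methylation was higher with DS3201: of 20,278 100-kb bins of sites over 1 kb from any gene, 1,986 (9.79%) rose and 23 (0.113%) fell, and the level went from 42.7% ± 0.31 to 47.4% ± 0.57. In 84.3% of these bins the difference was above 0, with a median of 4.84 points. The higher count was 2,520 without 5KO replicate 1, 1,341 without 5KO replicate 2, 2,077 without DS3201 replicate 1 and 697 without DS3201 replicate 2, and the lower counts were 56, 11, 20 and 14. Over all 10-kb bins the median difference was 3.38 points, with 81 higher (0.034%), 742 lower (0.308%) and 27,790 at an unadjusted p under 0.05. Over the same bins limma called 0 in either direction and edgeR 0.005% higher and 0.044% lower. Corrected for the apparent methylation of mitochondrial DNA, which was higher on protein-coding genes than on the control region and transfer RNA genes and so is not a measure of conversion alone, 752 bins (0.312%) were lower and 2,456 (1.02%) higher. Higher bins included chromosome 1, 57,070,001 to 57,080,000 (20.2% ± 1.15 to 60.1% ± 2.24), chromosome 1, 148,520,001 to 148,530,000 (2.5% ± 3.54 to 41.1% ± 5.29), and a bin in the potassium channel gene Kcnh7 on chromosome 2 (63,180,001 to 63,190,000; 25.1% ± 2.32 to 54.1% ± 7.71). Of the 742 lower bins 8, and of the 81 higher bins 19, were also called on sparse sites alone. Lower bins formed runs of 20 kb at Cdkn2c and Faf1 (chromosome 4, 109,660,001 to 109,680,000; 60.4% ± 7.45 to 13.7% ± 2.40), at Ppp1r35, Mepce and Zcwpw1 on chromosome 5 (54.6% ± 2.65 to 22.4% ± 3.25), and at Lrig1 on chromosome 6 (77.9% ± 11.2 to 39.6% ± 11.8). The share of lower bins was 0.063% without DS3201 replicate 2, 0.151% without 5KO replicate 2 and at most 0.451% without another library. The higher share was 0.043% without 5KO replicate 1, 0.009% without 5KO replicate 2, 0.015% without DS3201 replicate 1 and 0.001% without DS3201 replicate 2.

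With DS3201, 99 of 29,651 gene bodies rose and 336 fell. Of the falls 82, and of the rises 0, were among the 922 bodies with over 1.5 times the calls of like bodies in untreated 5KO cells, relative to the other groups. Rises included Hoxd10 (47.4% ± 4.08 to 65.3% ± 1.11), Chrna7, which encodes a nicotinic receptor subunit (15.3% ± 2.32 to 31.2% ± 3.27), Bmp5, a bone morphogenetic protein gene (19.9% ± 2.52 to 34.7% ± 0.96), and the transcription factor genes Ikzf1, Barx2 and Sim1 (42.3% ± 0.30 to 56.2% ± 1.66 for Sim1). Tgm6, Tmprss15 and Zfp982 rose by 15.3 to 16.01 points. The largest falls were in Hmgn2, a nucleosome binding protein gene (82.1% ± 3.01 to 7.19% ± 2.52), Junb (87.3% ± 9.04 to 16.7% ± 8.79), Ubb (87.8% ± 13.8 to 20.2% ± 0.57), Jund, Ier2, Ier3, Ier5, Zfp36l2, Hspe1 and Slc6a8. Their differences lay between −74.9 points for Hmgn2 and −64.4 points for Hspe1. The share called was 1.47%, and 0.492% without 5KO replicate 1, 0.105% without 5KO replicate 2, 0.556% without DS3201 replicate 1 and 0.003% without DS3201 replicate 2. An unadjusted p under 0.05 was reached by 5,332 bodies. With calls corrected for the apparent methylation of mitochondrial DNA, 493 bodies were lower and 1,404 higher.

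Of 14,734 gene-end windows 275 fell with DS3201 and 2 rose. The largest falls were Sqstm1 (94.9% ± 4.5 to 2.64% ± 0.31), Utp18, Ppp1r2, Mbtd1, Mogs, Rab24, Rnf217, Akirin2, Faf1 and Col1a1, the gene of the collagen I alpha 1 chain (86.0% ± 3.73 to 13.6% ± 19.2). Among these, the windows of Utp18 and Mbtd1 overlap and share calls. Cbx3, which encodes a heterochromatin protein 1, fell from 37.0% ± 8.55 to 1.72% ± 1.24, and Rbbp7, a PRC2 gene, from 86.7% ± 10.4 to 15.4% ± 6.84. The 2 rises were Zfp131 (8.9% ± 6.03 to 54.1% ± 13.3) and the predicted gene Gm46866 (9.86% ± 2.29 to 55.3% ± 11.2), the second named after its values were seen. Limma called 0 windows and edgeR 0.007%, and 2,053 windows had an unadjusted p under 0.05. With the mitochondrial correction 0.149% were called, and 0.0% in a quasi-binomial fit of the 2 groups alone. The share called was 1.88%, and 3.74% without 5KO replicate 1, 2.41% without 5KO replicate 2, 0.109% without DS3201 replicate 1 and 0% without DS3201 replicate 2. In the part of the window outside genes 74 of the 275 had enough calls, and 0 of these were lower by the quasi-binomial model, with a median of −17.6 points. Limma and edgeR were not run on those parts, and 219 of all 3,028 had an unadjusted p under 0.05.

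With DS3201 housekeeping bodies fell in 8 of 30 (14 adjusted over the list alone; camera adjusted p = 3.09e-12, adjusted p = 0.0233 with an estimated correlation), from a mean of 70.9% ± 3.51 to 49.7% ± 2.55. Fibroblast marker bodies fell in 4 of 30 (8 alone; 0.000408 and 0.0700 for the same tests), among them Lox, which crosslinks collagen (85.9% ± 3.68 to 45.1% ± 6.73), and Vim, and fibroblast windows in 4 of 18 (5 alone; 0.000608 and 0.134). H3K9 list bodies fell in 2 of 21, Cbx5 and Kdm3b (8 alone; 1.02e-05 and 0.106), and PRC2 list bodies in 0 of 13 by the quasi-binomial model (6 alone; 0.00206 and 0.169). Zfp genes fell in 6 and rose in 3 of 389 bodies (11 and 3 alone; 0.00168 and 0.249), and developmental genes fell in 2, among them Tbx20, and rose in 1 of 118 (2 and 1 alone; 0.991 and 0.994), with a median of 0.98 points and a mean of −0.81 points. Hoxd10 was the 1 Hox body of 37 that rose (1 and 1 alone for lower and higher; 0.996 for both tests). Olfactory and vomeronasal receptor bodies were not called singly (0 of 109 and 0 of 108 by the quasi-binomial model, 0 and 0 alone), and stood above other genes in camera (adjusted p = 0.00023 and 3.70e-06; adjusted p = 0.0268 and 0.0233 with an estimated correlation), with means of 33.1% ± 0.24 and 27.9% ± 0.45. Germline bodies likewise had 0 of 46 called (0 alone) and a mean from 55.8% ± 0.68 to 60.9% ± 0.02 (camera adjusted p = 0.00165, adjusted p = 0.0700 with an estimated correlation). By the quasi-binomial model 0 bodies were called, and 0 adjusted over the list alone, of defensins (camera adjusted p = 0.0745, adjusted p = 0.310 with an estimated correlation), immune markers (0.147 and 0.279), epithelial markers (0.330 and 0.421), protocadherins (0.00365 and 0.472), imprinted genes (0.917 and 0.935) and DNA methylation machinery (0.0230 and 0.333). Imprinted windows had a median of 1.0 points and a mean of −7.45 points with 0 of 20 called (camera adjusted p = 0.403, adjusted p = 0.476 with an estimated correlation).

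The untreated 5KO libraries differed from the others in where their calls fell. Over the body of Col1a1 (chromosome 11, 94,936,224 to 94,953,042) they held 3,840 methylated and 343 unmethylated calls, against 1,070 and 313 in WT, 1,088 and 447 in TKO, and 1,398 and 595 in DS3201-treated libraries. In the 1000 bp on each side of the gene the methylated calls were 43 in untreated 5KO and 43 in WT libraries. Junb held 1,328 methylated calls in untreated 5KO and 112 in DS3201-treated libraries, and 3 and 21 in its flanks. Of the 275 windows lower with DS3201, 83 were among the 2,329 of 14,734 windows with over 1.5 times the calls of like windows in untreated 5KO cells, relative to the other groups. Inside the gene, 147 windows with no other gene outside held 1.92 ± 0.095 times the calls per site of other CpG-rich windows in untreated 5KO libraries, against 1.10 ± 0.001 in WT, 1.08 ± 0.01 in TKO and 1.21 ± 0.03 with DS3201. Without that scale their calls per 1000 sites and 1,000,000 calls were 48.4 ± 21.7 in untreated 5KO and 55.3 ± 10.3 with DS3201, and those of other CpG-rich windows 25.5 ± 12.6 and 45.6 ± 7.42. Their unmethylated calls, relative to other CpG-rich windows, were 0.663 ± 0.026 in untreated 5KO, 0.999 ± 0.017 in WT, 1.08 ± 0.016 in TKO and 1.29 ± 0.038 with DS3201. The windows were chosen for a lower level with DS3201, which itself moves these values in untreated 5KO and DS3201-treated libraries.

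**Figure D4:**
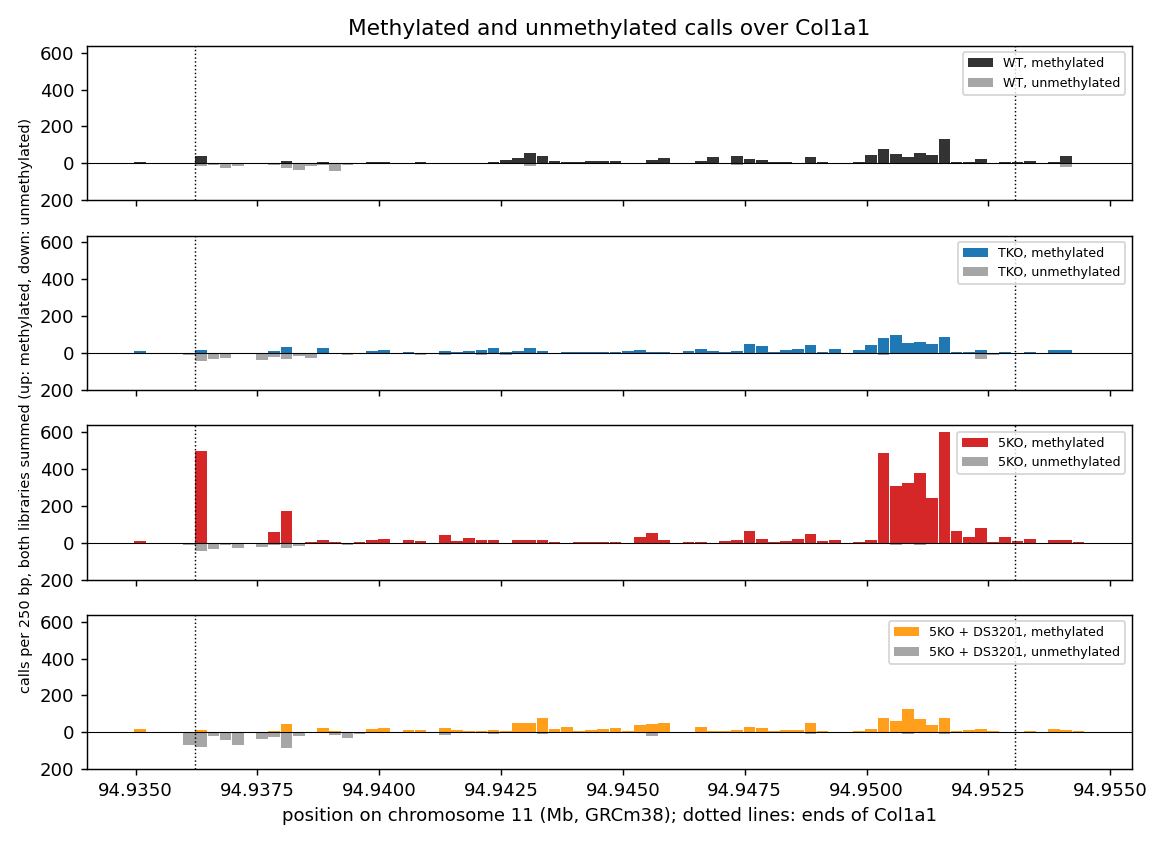
Methylated calls (upward) and unmethylated calls (downward) per 250 bp along Col1a1 on chromosome 11 (horizontal axis, position), summed over the 2 libraries of each group, with 1 panel per group and dotted lines at the gene ends. Methylated calls over the gene number 3,840 in untreated 5KO libraries and 1,070 to 1,398 in the other groups.

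Mitochondrial DNA, used above for a correction of the levels, was measured in the same way. Over mitochondrial protein-coding genes 1.77% ± 0.12 of calls were methylated in WT, 2.89% ± 0.68 in TKO, 10.6% ± 0.34 in untreated 5KO and 3.41% ± 0.17 in DS3201-treated libraries. Over the control region and transfer RNA genes the values were 0.564% ± 0.010, 0.697% ± 0.199, 1.16% ± 0.007 and 0.592% ± 0.106.

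**Figure D5:**
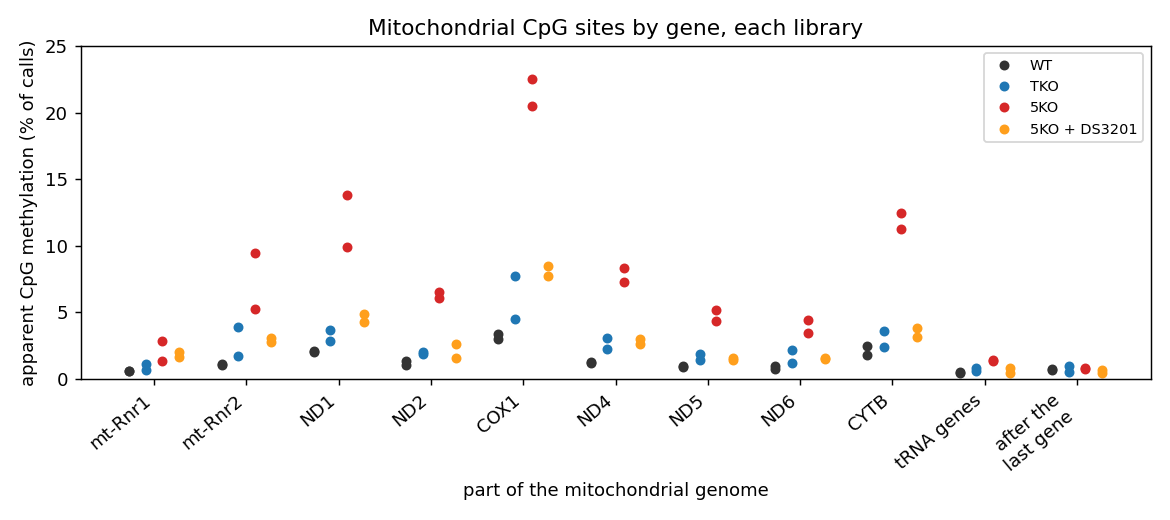
Methylated share of calls in percent (vertical axis) for features of the mitochondrial genome (horizontal axis), with 1 point per library and 1 colour per group. COX1 reads 21.5% in untreated 5KO libraries and 3.17% in WT, and the sites after the last gene 0.778% and 0.694%.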

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

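Chosen only after the result was seen were the tests of bisulfite conversion, transcript copies and gain of methylation for the extra methylated calls and of loss of methylation for the gene-end windows. The call profiles of Col1a1, Ubb and Junb had been seen before any test of the gene-end windows was written down.

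Mitochondrial genes, which the comparisons do not use, read above their WT level in other groups. COX1 stood at 3.17% ± 0.25 in WT, 6.10% ± 2.26 in TKO, 21.5% ± 1.44 in untreated 5KO and 8.11% ± 0.54 in DS3201-treated libraries. CYTB stood at 2.10% ± 0.47 in WT, 11.9% ± 0.87 in untreated 5KO and 3.48% ± 0.52 in DS3201-treated libraries. The ribosomal RNA genes stood at 0.582% ± 0.04 (mt-Rnr1) and 1.06% ± 0.05 (mt-Rnr2) in WT, and at 2.07% ± 1.06 and 7.34% ± 2.94 in untreated 5KO libraries.

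In untreated 5KO libraries genes such as Col1a1 and Junb held extra methylated calls. Incomplete bisulfite conversion alike at all sites is argued against as their whole cause by the control region and transfer RNA genes. These stood at 1.16% ± 0.007 against 0.564% ± 0.010 in WT, 0.599 points above, while the protein-coding genes were 8.82 points above. A failure of conversion limited to CpG-dense sites was not tested. A gain of methylation adds no reads if methylated and unmethylated fragments are recovered alike, which was not tested. That may not hold, since on the densest sites the library with fewer calls had the higher level in each group. Only under it is a gain argued against as the whole cause, by the ratio of calls over fibroblast marker windows to windows of like CpG density. The lower of the 2 untreated 5KO libraries exceeded all other libraries by at least 0.854. Without that scale both held at least 62.9 calls per 1000 sites and 1,000,000 calls against at most 54.3. Unconverted copies of transcripts among the reads stay open, with that ratio at 2.03 or more in both libraries and at 0.961 ± 0.071 for developmental gene windows. Against them, on the same scale epithelial marker windows also had more calls in untreated 5KO libraries (1.38 ± 0.002, and 1.14 ± 0.22 in WT), while housekeeping genes go both ways, with 1.14 ± 0.03 in windows (1.16 ± 0.23 in WT), 2.25 ± 0.585 at the other gene end (1.22 ± 0.16) and 1.99 ± 0.27 in bodies (1.23 ± 0.14). Such copies may account for part of the rises in bodies. Of these, 115 of 663, against 922 of all 29,651, had over 1.5 times the calls of like regions. Over the 663 bodies the median of relative calls against WT was 0.997, so the typical risen body held no excess of calls. The windows (37 of 159, and 2,329 of all 14,734, median 0.903 for the 159) say little. A gain of methylation in part of these genes stays open.

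The 275 gene-end windows lower with DS3201 than in untreated 5KO cells raise the same question. In 144 of them with calls on both sides of the gene end and no gene outside, the median difference was 63.6 points inside the gene and 16.5 points outside, a ratio of 0.259. Incomplete conversion would act alike on both sides. That ratio cannot decide on it, since the windows were chosen by their level difference in these same libraries. In the 3,017 other CpG-rich windows, untreated 5KO and DS3201-treated libraries stood at 27.3% ± 6.04 and 11.25% ± 0.659 inside the gene. Outside the gene they stood at 31.3% ± 5.46 and 24.001% ± 1.203. Incomplete conversion stays open, as do transcript copies, which lie inside genes. A loss of methylation with DS3201 cannot be told apart from such copies: calls per site inside the gene exceeded every other library by at least 0.624 in both untreated 5KO libraries relative to other CpG-rich windows, but unscaled, untreated replicate 2 held 33.03 per 1000 sites and 1,000,000 calls and DS3201 replicate 2 62.6. Such a loss may account for part or all of the falls. Only 83 of the 275, and 2,329 of all 14,734, had over 1.5 times the calls of like regions. Over whole windows the median of relative calls was 1.09. Unmethylated calls inside genes, which copies would not remove, were 0.663 ± 0.026 of those of other CpG-rich windows in untreated 5KO libraries. The windows were chosen by their levels in these same libraries, which lowers that value by itself, so it decides nothing.

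Methylation away from genes was higher with DS3201 than in untreated 5KO cells. A difference in which sites were covered is argued against by 1,751,621 gene-free sites with calls in all 4 libraries, at 44.5% ± 0.16 without and 48.7% ± 0.29 with DS3201, a difference of +4.19 points. That DS3201 treatment may raise methylation in such regions is an open hypothesis. It was found and tested on the same 2 libraries against 2 of 1 line, and a difference between cultures was not tested.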

How the results depend on the processing

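Lists of 4 values run in the order TKO with WT, 5KO with WT, 5KO with TKO, and DS3201-treated with untreated 5KO. Where a value moved, the cause was not tested. Chosen after seeing the data were the tests on gene bodies, sparse sites, sites or bins away from genes, parts of windows outside genes, the other gene end, 2 groups alone and regions without excess calls, and the mitochondrial correction of regions. Under other settings 113 values stayed within the spread between libraries or 1.5 times the reported count, 106 moved by more and 1 changed sign. With 1 library left out 49 stayed and 47 moved. A library left alone in its group is assumed to vary like the other groups.

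Genome-wide differences kept their sign under each setting but 1. Unweighted means of sites with at least 5 calls gave −9.53, −19.3, −9.81 and 3.503 points. Sites with calls in all 8 libraries gave −4.27, −9.48, −5.21 and −0.0868 points. With sites of extreme coverage removed they were −10.3, −19.4, −9.07 and 3.07 points. With the mitochondrial correction they were −9.68, −21.03, −11.4 and 4.92 points. Sparse sites gave −11.03, −21.1, −10.04 and 4.17 points. Sites outside genes gave −14.2, −26.7, −12.4 and 5.82 points.

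Shares of bins moved with bin size and threshold. With 100-kb bins the lower share was 54.1% (TKO with WT), 46.1% (5KO with TKO) and 1.56% (DS3201). The higher share was 0.282% (TKO with WT), 0.399% (5KO with WT) and 6.999% (DS3201). A difference of at least 25 points left 0.112%, 0.278% and 0.682% higher in the first 3 comparisons and 9.50% lower in 5KO against TKO. Bins without any gene had 45.7% lower and 0.231% higher (TKO with WT), 0.407% higher (5KO with WT), and 0.012% lower and 0.097% higher (DS3201). For 100-kb bins of sites over 1 kb from genes these were 58.4% lower, 0.385% higher, 51.8% lower (5KO with TKO), and 0.113% lower and 9.79% higher (DS3201). Sparse sites gave 0.617% higher in 5KO against WT and 0.007% lower and 0.019% higher with DS3201. Limma gave 0.275% higher in TKO cells and 0.0% either way with DS3201, where edgeR gave 0.044% and 0.005%. With the 10-point minimum measured from the median difference and the adjusted p still against WT, 5KO had 31.1% below and 4.69% above it. The mitochondrial correction gave 0.687% higher (5KO with WT), 33.3% lower (5KO with TKO) and 1.02% higher (DS3201), and calls thinned to the shallowest library 0.02% higher with DS3201. Of bins higher in TKO cells 44.7% were higher in 5KO cells, and 29.2% with 100-kb bins. With 1 library left out, lower shares were 11.4% to 18.8%, 52.6% to 57.5%, 6.32% to 10.2% and 0.063% to 0.451%. Higher shares were 0.2% to 0.446%, 0.797% to 1.31%, 0.472% to 1.10% and 0.001% to 0.043%. Of the 69,513 bins lower in TKO cells 49,280 were also lower by limma and 60,017 by edgeR. Of the 742 lower with DS3201 these were 0 and 107, and 8 with sparse sites.

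The share of gene-end windows called was 0.025%, 0.763%, 1.501% and 4.86% with at least 50 calls. By limma it was 0.014%, 2.43%, 0.0% and 0.0%, and by edgeR 0.0%, 0.0%, 0.0% and 0.007%. It was 0.014%, 10.3%, 0.193% and 0.997% with 2000 bp on each side. At the other gene end it was 0.519%, 10.998%, 0.925% and 0.519%, and outside genes 0.066%, 0.033%, 0.0% and 0.0%. Fits of 2 groups alone called 0.0% in each comparison, and a difference of at least 25 points 0.0% in TKO against WT. With the mitochondrial correction the share was 0.014% in both 5KO comparisons with DMSO groups and 0.149% with DS3201. With 1 library left out it was 0.0% to 0.007%, 0.0% to 2.29%, 0.0% to 2.12% and 0.0% to 3.74%. Camera called 4, 7, 6 and 7 lists in windows, and 0 in each comparison with an estimated correlation. It called 1, 1, 0 and 0 outside genes, and 7 and 13 in gene bodies for the first 2. With 1 library left out it called 3 to 4, 6 to 7, 3 to 8 (3 without TKO replicate 1) and 2 to 8 lists (2 without DS3201 replicate 2, 3 without 5KO replicate 2).

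The share of gene bodies called was 6.33%, 5.21% (5KO with TKO) and 0.715% (DS3201) with at least 25 points, and 6.40% with DS3201 under the mitochondrial correction. With 1 library left out it was 7.05% to 8.95%, 29.1% to 34.2%, 8.33% to 11.4% and 0.003% to 0.556%. Of 120 results for named genes 0 changed direction, and 24 were called without each library in turn.

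Replicate numbers of different groups share only a number, and the differences between replicates 1 and 2 correlated across bins between groups at −0.024 to 0.046. A replicate block lowered the share of called windows in 5KO against WT to 0.054% and of gene bodies with DS3201 to 0.965%, and left every other count within 1.5 times. A low number of called windows in TKO against WT says little. Simulated differences of 40 points there were found in 0% of windows, 79% of gene bodies and 82% of bins. The simulation held 100 changed regions of each size and did not vary depth, so it does not tell what limits the windows.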

Other observations

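The strata, chromosomes and stretches below were chosen after the data were seen, and no test was run on them. Of 60,332 bins at 60% to 80% in TKO cells 31.5% were lower in 5KO than in TKO cells, and their level went from 70.5% ± 0.05 to 57.6% ± 0.14. Of 52,728 bins above 80% in TKO cells 12.5% were lower, and their level went from 88.2% ± 0.05 to 82.9% ± 0.03. Bins were chosen by the TKO level itself, so part of this comes from its sampling error. Across chromosomes the mean difference of bins in TKO against WT ran from −17.3 points on chromosomes 14 and X to −8.59 points on chromosome 10. In 5KO against TKO it ran from −12.3 points on chromosome 10 to −6.77 points on chromosome 11. Bins above 80% made up 33.2% in WT, 21.9% in TKO, 17.3% in 5KO and 17.98% in DS3201-treated cells.

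A few short stretches of extreme coverage took up many calls. A stretch of chromosome 2 (98,662,264 to 98,667,325; 65 sites) stood at 89.4% ± 0.07 in WT, 89.7% ± 0.37 in TKO, 85.4% ± 0.04 in 5KO and 86.4% ± 0.28 in DS3201-treated libraries. A stretch of chromosome 9 (3,000,031 to 3,007,635) stood at 89.9% ± 0.12, 90.6% ± 0.20, 87.8% ± 0.60 and 87.7% ± 0.57. On chromosome 11 (3,184,275 to 3,199,986) the levels were 70.1% ± 1.62, 71.7% ± 3.42, 52.8% ± 4.30 and 61.8% ± 0.73. On chromosome 17 (39,843,001 to 39,848,822; 570 sites) they were 23.2% ± 0.02, 26.9% ± 1.81, 38.8% ± 1.93 and 20.3% ± 1.25.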
